A study of Mus musculus with 29 samples.

How the data were processed

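The series holds 29 mouse RNA sequencing libraries: 20 labelled poly(A) RNA (10 primary NPC, 2 Six2-negative and 8 NPC line libraries) and 9 labelled total RNA from medium withdrawal. For the 20, reads were aligned with STAR and summarised with Cufflinks on the mm9 mouse genome, per the submitters' processing notes, which give no versions. For the 9 withdrawal libraries the aligner, the counting tool and the genome build are not given in the sources used here. The authors deposited 1 table of RPKM values per gene symbol for all libraries, and a list of 1217 symbols named as NPC signature genes. RPKM divides by transcript length and by the total of mapped reads and makes no other correction between libraries, so a group of very abundant transcripts in a library lowers the values of its other genes.

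The table has 23947 lines. In 18 libraries the values of the last 2 lines were shifted, and these lines were left out for every library. The libraries with and without the shift form 2 sets of 18 and 11. All P80 lines and withdrawal libraries fall in the larger set and all P20 lines in the smaller, while the primary NPCs of every age but E12.5, and the Six2-negative cells, have 1 library in each. Symbols turned into calendar dates, 27 in the table and 4 in the signature list, were left out too. No library pair was a duplicate. The highest Pearson correlation of log2 values was 0.9853, between the P1 line at P80 and the E11.5 line at P80. No gene had identical non-zero values in that pair. Of 15 housekeeping genes looked at, none was at 0 in any library, and among 4456 genes with a median RPKM of at least 20, 59 were at 0 in at least 1 library. A gene at 0 is therefore described as listed at 0.

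Depth was estimated from the table. For each library the value of 1 read was taken from the spacing of low values multiplied by transcript length (mm9 annotation, GENCODE M1), and 64.8 to 74.6% of those low values lay within 10% of a whole number of reads. The estimates are 11.8 to 32.9 M reads for primary NPCs, 20.8 and 33.3 M reads for Six2-negative cells, 6.7 to 20.7 M reads for lines at P20, 15.3 to 24.6 M reads for lines at P80 and 6.8 to 17.1 M reads for withdrawal libraries. No count test was run, since whole counts could not be recovered for nearly all genes. Transcripts at an RPKM under 1 rest on few reads in the shallow libraries.

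Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with moderated statistics and a variance trend, two-sided, and Benjamini-Hochberg adjustment over the genes with an RPKM of at least 1 in at least 2 libraries of the fit; an adjusted p under 0.05 was called. The 12 primary and Six2-negative libraries formed 1 fit (13574 genes). The 8 primary libraries of the 4 ages with lines and the 8 lines formed another (13612 genes), with age of origin as a term. The late against early contrasts used the 8 primary libraries and 4 line averages, the mean log2 value of P20 and P80 per line, so 2 lines stand in each age class. Where an age or condition is left with 1 library, that library is assumed to vary like the other groups. The labels do not say that replicate libraries came from separate animals or cultures, and the lines are 1 per age, so p-values measure the spread between these samples, which may be technical in part.

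The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, per comparison, up to 10 higher and 10 lower genes with the largest fold change among those with adjusted p under 0.05, a log2 change of at least 1, a mean RPKM of at least 5 in a compared group and no overlap between the libraries of the groups. Predicted and unnamed genes are passed over, up to 4 called members per list are added, and Six2, Cited1, Wnt4 and Lef1 are given in every tested comparison. Some genes that this rule selects are not reported here. For withdrawal, up to 5 genes per direction and component had a log2 difference of at least 1 on each day and an RPKM of at least 5. Genes shown for their level in each library were chosen after the values were seen where the rule does not name them. Lists were tested with camera at a preset correlation of 0.01, adjusted over 31 lists per comparison, and again with an estimated correlation. Calls that hold with the estimated correlation are glycolysis and hypoxia genes and p53 targets at P20 and P80, and cholesterol synthesis genes and FGF and ERK targets at P80. Lists in withdrawal libraries were placed among 10000 random lists matched in size and mean level in 20 bins.

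Each test except that of late against early primary cells was tested on simulated data made from the spread of the real libraries, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. Of these, 52% and 93% were recovered for Six2-negative cells (13048 genes), 46% and 87% for P1 against E11.5 (13036 genes), 53% and 85% for the F test (13049 genes), 79% and 95% for P20 (13146 genes), 80% and 94% for P80 (13111 genes), 71% and 94% for P80 against P20 (13128 genes), 47% and 93% for late against early lines (13146 genes), and 28% and 79% for the difference between lines and primary cells (13153 genes). Between 0 and 14 unchanged genes were called in these runs. The changed genes were drawn from those with a mean log2 value above 2 and were shifted alike in all libraries of a group. Libraries were otherwise drawn independently, without differences between lines or ages.

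Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at an RPKM of 5, trimmed-mean factors computed on RPKM, quantile normalization, no variance trend, a minimum fold of 2, each library left out in turn, a replicate block for the primary libraries, no age term, the line as a random effect, all 20 libraries in the fit, lines of 1 passage only, and the E13.5 lines as the reference for withdrawal. Chosen after seeing the data were a term for the set of the shifted lines, E16.5 in place of P1, early ages only for the line comparisons, and the separate late against early contrasts. Gene positions are from the mm9 annotation.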

Results

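RNA sequencing profiled nephron progenitor cells (NPCs), the Six2-expressing cap mesenchyme cells that give rise to the nephrons of the kidney, in 29 mouse libraries. Primary NPCs were sampled at embryonic days E11.5, E12.5, E13.5 and E16.5 and at postnatal day P1, with 2 libraries at each age. A further 2 libraries held E12.5 kidney cells labelled Six2-negative. Cultured NPC lines derived at each of these ages except E12.5 were each sampled once at passage 20 (P20) and once at passage 80 (P80), giving 4 libraries per passage. The lines grew as aggregates in a medium named NPSR. The last 9 libraries came from cultures labelled E13.5 in which heparin, the ROCK inhibitor Y27632, BMP7 or the GSK3 inhibitor CHIR was missing from the medium for 4 or 8 days, or LIF for 8 days, with 1 library per condition. The mice carried a Six2-GCE allele, which places a fusion of green fluorescent protein and an inducible Cre recombinase under the control of Six2. The deposited values are RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library) for 23918 usable gene symbols. The depth estimated from the smallest steps between low values ran from 6.7 M (1e6) reads in the P1 line at P20 to 33.3 M reads in Six2-negative library 1, with a median of 16.2 M reads over the 29 libraries. An RPKM of 1 in a transcript of 2 kb then stood for an estimated 13.4 to 66.6 reads. Fold changes below are on the log2(RPKM + 1) scale with standard errors (SE), and they understate the change of genes with low values. In the tested comparisons, genes named for their fold change had no overlap between the libraries of the compared groups, except where they are given as members of a list or did not pass.

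The first question was how far cultured lines, primary NPCs and Six2-negative cells differed as whole transcriptomes. Lines resembled one another more than they resembled primary cells. The median Spearman correlation across genes was 0.953 between lines (28 pairs, 0.927 to 0.975), 0.928 between primary libraries (45 pairs, 0.818 to 0.975) and 0.881 between a line and a primary library (80 pairs, 0.8 to 0.905). Six2-negative libraries had a median of 0.9 with primary NPCs and 0.857 with lines. Genes are not independent replicates, and no test was attached to these correlations. The principal component with the largest share of the variance (34.1%) placed the 8 line libraries between 49.6 and 61.5 and the 12 primary and Six2-negative libraries between -49.2 and -30.2. The component with the next largest share (17.2%) spread the primary libraries, from -46.7 in E13.5 library 2 to 91.1 in P1 library 1.

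**Figure D1:**
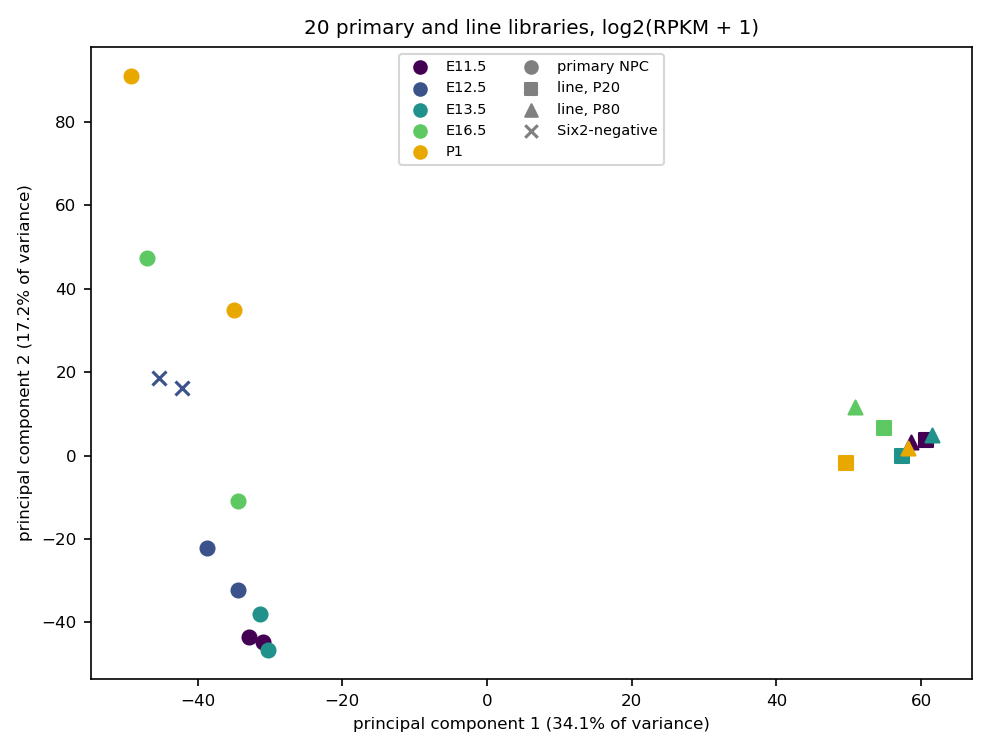
Principal components of the 20 primary, Six2-negative and line libraries on log2(RPKM + 1) values; colour gives the age or age of origin and the symbol gives the kind of cell. The 8 line libraries lie at 49.6 or higher on the horizontal component, which holds 34.1% of the variance, and the other 12 lie at -30.2 or lower.

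At E12.5, cells labelled Six2-negative were compared with NPCs of the same age to define what sets progenitors apart from the rest of the kidney. Six2 itself, the transcription factor that maintains the progenitor state (mm9 chromosome 17, 86083608 to 86087594, minus strand), had a mean RPKM of 5.40 ± 2.76 (SD, n = 2) in Six2-negative cells and 230.5 ± 7.71 (n = 2) in NPCs. Its log2 fold change was -5.25 ± 0.36 (SE, adjusted p = 0.000181). Progenitor regulators fell with it in the Six2-negative cells: Eya1, a transcriptional coactivator required for kidney formation, by -4.88 ± 0.38, and the homeobox genes Uncx by -4.86 ± 0.41 and Meox2 by -4.17 ± 0.35. The growth factor gene Fgf8, a member of the early nephron differentiation list, was lower too (-4.31 ± 0.26). Crym (-4.97 ± 0.25), Rspo1, which encodes a secreted enhancer of Wnt signalling (-4.59 ± 0.32), Spock2 (-4.21 ± 0.36) and Pcp4 (-3.83 ± 0.19) were also among the lower genes. The genes with the largest rise encode globins. Hba-a1 (7.36 ± 0.94) reached 843.5 ± 525 RPKM in Six2-negative cells against 4.02 ± 2.84 in NPCs, and Hba-x (6.77 ± 0.86), Hbb-bh1 (6.32 ± 0.57), Hbb-bt (6.16 ± 0.76) and Hbb-b1 (6.05 ± 0.89) were likewise higher. Globin genes have near-identical copies, so the split of reads among them is uncertain.

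Of 30 cap mesenchyme genes measured, 24 fell and 1 rose in Six2-negative cells, also when adjusted over the list alone (median log2 change -1.65, adjusted p = 9.28e-22 by camera, adjusted p = 0.211 with an estimated correlation). Cited1, a marker of uncommitted progenitors, fell by 1.65 ± 0.27 (adjusted p = 0.00573), a call that ended without Six2-negative library 2 (-1.57, adjusted p = 0.0618). Among early nephron differentiation genes, 4 rose and 8 fell out of 21 (5 and 9 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.084). Wnt4, which drives the transition from mesenchyme to epithelium, fell by 2.29 ± 0.41, and this call ended without E12.5 library 1 (-2.01, adjusted p = 0.0504) or Six2-negative library 2 (-1.88, adjusted p = 0.0856). Lef1, a transcription factor of the Wnt pathway, differed by 0.66 ± 0.30 (adjusted p = 0.202).

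Marker lists of several other cell types rose. Macrophage genes had a median of -1.42 (adjusted p = 0.0415; adjusted p = 0.71 with an estimated correlation) with no member called. Endothelial genes had a median of 1.93 without passing as a list (adjusted p = 0.0883), and the only member called was lower. All 10 erythroid genes passed (median 4.85, adjusted p = 1.94e-09; adjusted p = 0.211 with an estimated correlation; 10 adjusted over the list alone). Of 18 renal stroma genes, 13 rose and none fell (15 and 0 adjusted over the list alone; median 2.44, adjusted p = 5.49e-10; adjusted p = 0.307 with an estimated correlation). Pdgfrb, a receptor of stromal cells and pericytes, rose by 3.42 ± 0.50. Fibrillar matrix genes rose in 13 of 15 cases (14 adjusted over the list alone; adjusted p = 1.94e-09; adjusted p = 0.448 with an estimated correlation). Their collagen Col1a1 rose by 3.96 ± 0.69, a call that ended without E12.5 library 2 (3.33, adjusted p = 0.0727) or Six2-negative library 2 (3.66, adjusted p = 0.0737). Ureteric bud genes rose in 6 of 15 cases (7 adjusted over the list alone; adjusted p = 0.000709; adjusted p = 0.592 with an estimated correlation). Among them, the GDNF receptor Ret stood at 3.41 ± 0.46. YAP targets rose in 5 of 11 cases (7 adjusted over the list alone; adjusted p = 0.000949; adjusted p = 0.211 with an estimated correlation), among them Tgfb2 (2.06 ± 0.21) and Amotl2 (1.10 ± 0.17). Actin and SRF targets rose in 8 of 17 cases and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.000691; adjusted p = 0.45 with an estimated correlation); the member that fell was Tpm2 (-2.20 ± 0.27). Wnt targets rose in 7 of 14 cases and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0139; adjusted p = 0.499 with an estimated correlation). Posterior Hox genes, which set position along the body axis, fell in 5 of 14 cases and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00054; adjusted p = 0.353 with an estimated correlation). Among them, Hoxa11 stood at -1.11 ± 0.17 and Hoxb9 at -1.10 ± 0.15. FGF and ERK targets fell in 3 of 15 cases (3 adjusted over the list alone; adjusted p = 0.0132; adjusted p = 0.499 with an estimated correlation), among them Il17rd (-1.48 ± 0.21).

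Over all 13574 genes tested with limma, 1846 passed an adjusted p of 0.05, 1259 higher and 587 lower in Six2-negative cells. The number of calls rested on single libraries: 476 passed without E12.5 library 2, 911 without Six2-negative library 1 and 400 without Six2-negative library 2. The authors' deposited list of NPC signature genes could be examined for 1186 symbols. Of the 313 with a lower mean in Six2-negative cells, 263 were called lower (276 adjusted over the list alone), and of the 873 with a higher mean, 649 were called higher (792 adjusted over the list alone). The list appears to have been chosen on these libraries, since 98.3% of its 1162 symbols with non-zero means lay at least 2-fold apart in them, so these counts are not independent evidence of direction.

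**Figure D2:**
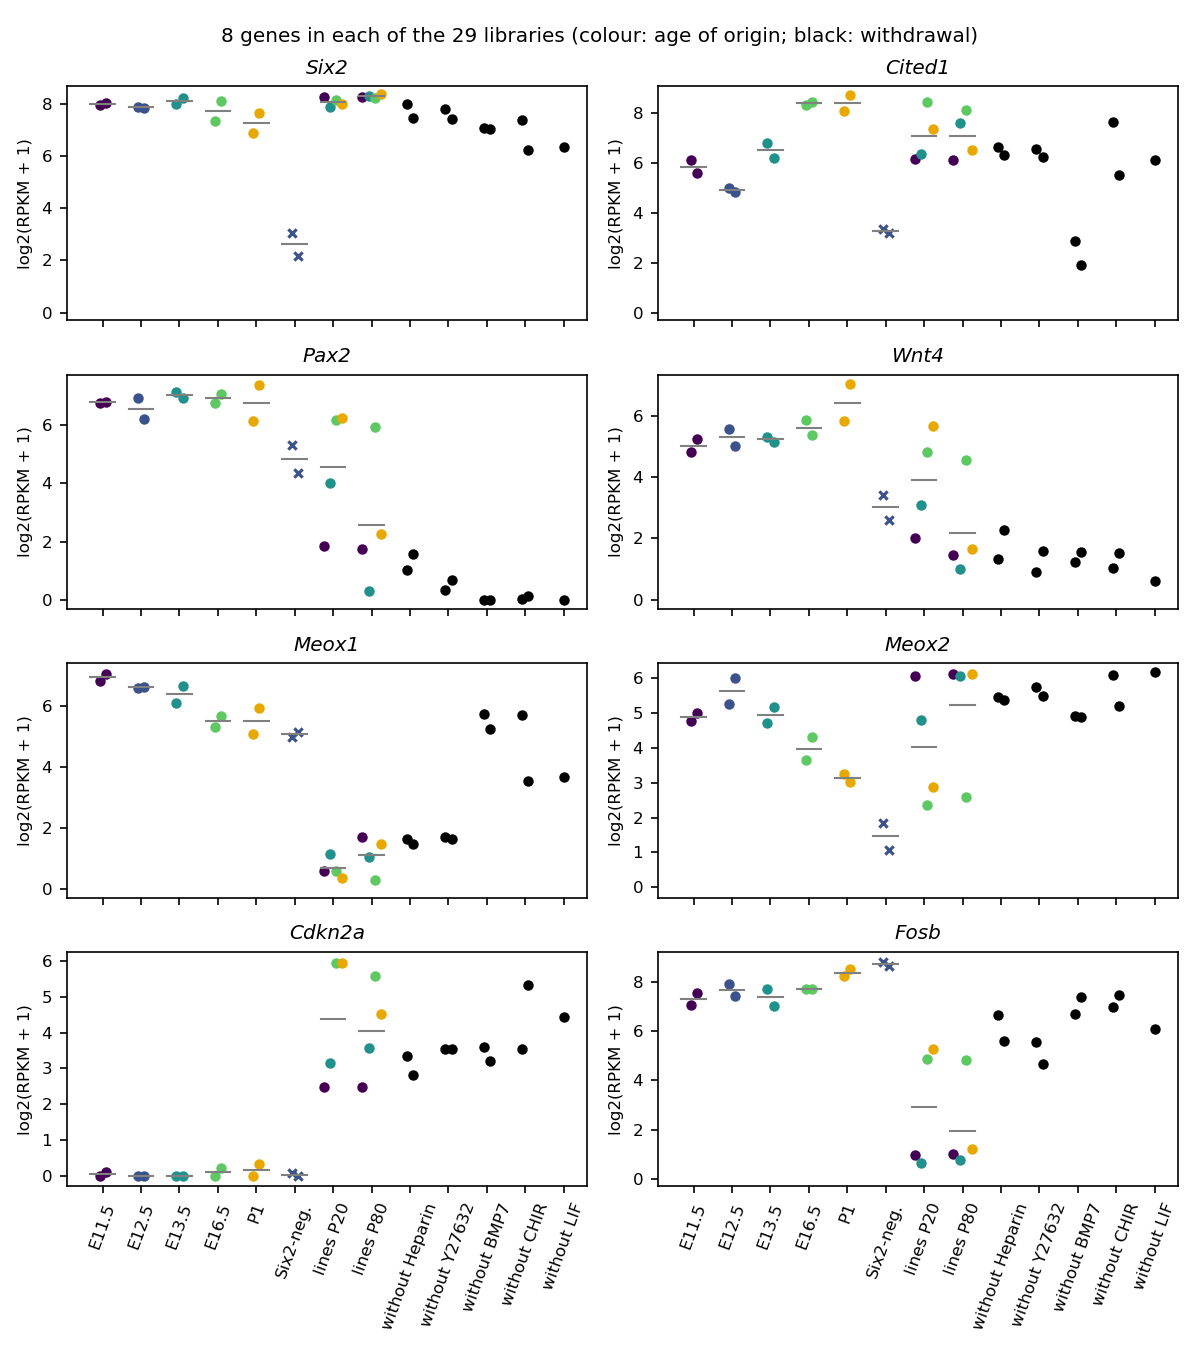
Levels of 8 genes as log2(RPKM + 1) in each of the 29 libraries, with colour for age of origin, crosses for Six2-negative cells, grey lines for group means, and black points for withdrawal libraries, day 4 left of day 8. Six2 lies between 116.7 and 328.6 RPKM in all primary NPC and line libraries and at 7.35 RPKM or lower in Six2-negative cells, while Pax2 in the lines runs from 0.241 to 73.3 RPKM.

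The ages of primary NPCs were compared to follow the progenitors from the start of kidney development to the end of their existence soon after birth. Libraries of P1 held less of cell cycle and Lin28 axis transcripts than those of E11.5, and more of tubule, stroma and interferon response transcripts. Whether these came from the progenitors themselves was not tested, and no list call of this comparison held with an estimated correlation. Arg1, which encodes arginase (mm9 chromosome 10, 24635014 to 24647276, minus strand), fell from 49.1 ± 4.35 RPKM (SD, n = 2) at E11.5 to 0.434 ± 0.0563 (n = 2) at P1, a log2 change of -5.12 ± 0.37 (SE, adjusted p = 0.000167). The imprinted cell cycle inhibitor Cdkn1c fell from 590.7 ± 0.772 to 74.3 ± 3.01 RPKM (-2.98 ± 0.17). Crmp1 (-4.22 ± 0.26), Cpa1 (-4.21 ± 0.23), the retinoic acid binding protein gene Crabp2 (-3.77 ± 0.30), the growth factor gene Pgf (-3.67 ± 0.38) and Moxd1 (-3.51 ± 0.29) fell as well. In the other direction, Penk, which encodes proenkephalin, rose from 0.816 ± 0.0138 to 160.7 ± 21.2 RPKM (6.47 ± 0.72, adjusted p = 0.000972). Fxyd2, a regulatory subunit of the sodium pump of kidney tubules, rose by 7.73 ± 0.96, the pump subunit Atp1b1 by 6.01 ± 1.01, Spp1 by 7.13 ± 1.27, Igfbp7 by 6.81 ± 0.70 and Ly6a by 5.94 ± 0.77. S100g, Kap and Tmem213 were listed at 0 in both E11.5 libraries and averaged 1840, 72.0 and 106.1 RPKM at P1. The 2 libraries at P1 differed widely in such genes: S100g had an SD of 2350 and Fxyd2 an SD of 1190.

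Proliferation genes fell together: 23 of 26 cell cycle genes were lower at P1 and none was higher (23 and 0 adjusted over the list alone; median -0.98; adjusted p = 0.314 with an estimated correlation), among them the mitotic kinases Aurka (-2.03 ± 0.28) and Plk1 (-1.93 ± 0.33) and the cyclin gene Ccne1 (-1.69 ± 0.18). Of 14 genes of the Lin28 and let-7 axis, which controls developmental timing, 12 fell and none rose (median -1.26; adjusted p = 0.314 with an estimated correlation). They included the RNA binding protein genes Igf2bp3 (-2.84 ± 0.30) and Igf2bp1 (-2.37 ± 0.15), Igdcc3 (-2.39 ± 0.30) and Hmga2 (-1.85 ± 0.30). Cholesterol synthesis genes fell in 14 of 19 cases (median -0.74; adjusted p = 0.153 with an estimated correlation). Among them, Fdps stood at -1.37 ± 0.13 and Fdft1 at -1.35 ± 0.12. Imprinted genes fell in 13 of 24 cases and 1 rose (14 and 2 adjusted over the list alone; adjusted p = 0.179 with an estimated correlation). Among them, Nnat stood at -2.71 ± 0.26 and Mirg at -1.99 ± 0.39.

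Interferon response genes rose in 13 of 16 cases (14 adjusted over the list alone; median 1.89; adjusted p = 0.477 with an estimated correlation), including Isg15 (3.11 ± 0.61), Irf7 (2.78 ± 0.54) and Oasl2 (2.77 ± 0.39). Early nephron differentiation genes rose in 12 of 21 cases and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation). Among them, Clec18a stood at 2.66 ± 0.43. Wnt4 rose by 1.41 ± 0.41, a call that ended without E11.5 library 1 (1.19, adjusted p = 0.159), E11.5 library 2 (1.62, adjusted p = 0.0697) or P1 library 2 (0.81, adjusted p = 0.12). Markers of differentiated or neighbouring cells moved in the same comparison. Tubule genes rose in 9 of 16 cases (14 adjusted over the list alone; adjusted p = 0.477 with an estimated correlation), among them Umod, the uromodulin gene of the thick ascending limb, at 5.41 ± 0.93. Stroma genes rose in 11 of 18 cases and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.59 with an estimated correlation). Among them, smooth muscle actin Acta2 stood at 4.89 ± 0.67. Fibrillar matrix genes rose in 12 of 15 cases (13 adjusted over the list alone; adjusted p = 0.477 with an estimated correlation), with Bgn at 4.19 ± 0.75 and Col6a1 at 3.52 ± 0.59, and ureteric bud genes rose in 7 of 15 cases (4 with quantile scaling; 8 adjusted over the list alone; adjusted p = 0.618 with an estimated correlation). The macrophage list passed as a set (adjusted p = 0.0168; adjusted p = 0.652 with an estimated correlation) with none of its members called.

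Signalling targets also moved. Immediate-early and heat shock genes rose in 9 of 16 cases (10 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). Among them, Nr4a1 stood at 2.56 ± 0.34 and Btg2 at 2.38 ± 0.35. YAP targets rose in 8 of 11 cases (5 with quantile scaling; 9 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation). Among them, Ctgf stood at 2.66 ± 0.49 and Axl at 2.20 ± 0.21. LIF and STAT3 targets rose in 8 of 13 cases (adjusted p = 0.314 with an estimated correlation), with Cish at 2.11 ± 0.22, and Wnt targets rose in 7 of 14 cases and 1 fell (adjusted p = 0.477 with an estimated correlation). Among them, Tnfrsf19 stood at 2.11 ± 0.17. Cap mesenchyme genes moved both ways: 5 of 30 rose and 9 fell, and the list did not pass. Tmem100 (3.12 ± 0.23) and Cited1 (2.56 ± 0.27) rose, Osr1 (-2.59 ± 0.28) and Meox2 (-1.75 ± 0.35) fell, and Six2 (-0.71 ± 0.36, adjusted p = 0.149) and Lef1 (0.02 ± 0.30, adjusted p = 0.962) did not pass.

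In total 4769 of 13574 genes passed between P1 and E11.5, 2369 higher and 2400 lower at P1. With quantile scaling of the libraries, which moved the median of all genes from 0.04 to -0.12, the share of higher calls changed from 49.7% to 37.3%. Without E11.5 library 1 the count was 1427, without E11.5 library 2 it was 2133 and without P1 library 1 it was 2334. Fewer genes passed between neighbouring ages early than late. There were 4 between E12.5 and E11.5, 5 between E13.5 and E12.5, 84 between E16.5 and E13.5 and 879 between P1 and E16.5. The steps are of unequal length, and all share the spread of the 12 libraries in the fit. A low count therefore does not show that 2 ages were alike. An F test over the 5 ages called 3330 genes, of which 1472 had their highest mean at P1 and 679 at E11.5. Its count was 1231 without E11.5 library 1, 1445 without E11.5 library 2, 2183 without E12.5 library 1, 1609 without E12.5 library 2, 1578 without E13.5 library 1, 1515 without E13.5 library 2, 1734 without P1 library 1 and 5632 without P1 library 2.

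Lines at P20 were compared with the 8 primary libraries of the matching ages, with age as a term, to ask which features of NPCs long-term culture keeps. Six2 was not lower in lines: it averaged 267.6 RPKM in the 4 lines at P20, 310.7 at P80 and 225.8 in primary cells (log2 change 0.29 ± 0.19, adjusted p = 0.255 at P20; 0.52 ± 0.19, adjusted p = 0.0515 at P80). At P80 Six2 stood near the limit and was called higher with trimmed-mean factors (0.64, adjusted p = 0.0242) or quantile scaling (0.54, adjusted p = 0.0282), and without E13.5 library 2 (0.58, adjusted p = 0.0378), E16.5 library 2 (0.58, adjusted p = 0.0347) or P1 library 1 (0.40, adjusted p = 0.0421). Cited1 did not pass (-0.22 ± 0.35, adjusted p = 0.653 at P20; -0.21 ± 0.35, adjusted p = 0.656 at P80). Glycolysis genes and p53 targets were higher in culture. Slc2a3, which encodes the glucose transporter GLUT3 (mm9 chromosome 6, 122677827 to 122751658, minus strand), rose to 169.7 ± 78.8 RPKM (SD, n = 4) at P20 from 2.35 ± 1.39 (n = 8) in primary cells, a log2 change of 5.64 ± 0.34 (SE, adjusted p = 1.58e-07). The cell cycle inhibitor gene Cdkn1a (mm9 chromosome 17, 29227924 to 29237667, plus strand) rose to 229.4 ± 82.8 from 9.88 ± 9.69 RPKM (4.69 ± 0.34, adjusted p = 6.22e-07). Anxa1 (5.08 ± 0.75), Matn1 (4.96 ± 0.26), the phosphofructokinase gene Pfkp (4.92 ± 0.39), Bcl3 (4.89 ± 0.23), Insl3 (4.84 ± 0.35) and Aldoc (4.60 ± 0.26) also rose. The homeobox gene Meox1 (mm9 chromosome 11, 101738824 to 101755688, minus strand) fell to 0.619 ± 0.412 RPKM from 74.1 ± 36.3 (-5.41 ± 0.27, adjusted p = 2.96e-08). The immediate-early gene Fosb (-4.74 ± 0.68), the retinal reductase gene Dhrs3 (-4.66 ± 0.39), the transcription factor genes Foxd2 (-4.36 ± 0.27) and Nr2f1 (-4.34 ± 0.18), and Hsd11b2 (-4.30 ± 0.36) fell as well.

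Of 22 glycolysis and hypoxia genes, 21 rose at P20 and none fell (21 and 0 adjusted over the list alone; median 2.40, adjusted p = 2.86e-21, and adjusted p = 0.00427 with an estimated correlation). They included the hypoxia-induced genes Egln3 (4.36 ± 0.59) and Car9 (4.08 ± 0.31), and the member that did not pass was Hk1 (0.19 ± 0.16). Targets of p53 rose in 16 of 20 cases (18 adjusted over the list alone; median 1.36, adjusted p = 1.28e-14, and adjusted p = 0.0195 with an estimated correlation). Among them, Ddit4l stood at 2.91 ± 0.13, Ccng1 at 2.62 ± 0.24 and Eda2r at 2.59 ± 0.19. Cyclin-dependent kinase inhibitors rose in 4 of 8 cases and 1 fell (4 and 0 with trimmed-mean factors, 4 and 1 adjusted over the list alone). The list passed (adjusted p = 0.0104 by camera, adjusted p = 0.0737 with an estimated correlation). Besides Cdkn1a, Cdkn2a (4.31 ± 0.49) and Cdkn2b (2.88 ± 0.22) rose. Over the 26 cell cycle genes, 2 rose and 3 fell (4 and 1 with trimmed-mean factors; none adjusted over the list alone), and the list did not pass (median 0.04, or 0.17 with trimmed-mean scaling; adjusted p = 0.754). Cholesterol synthesis genes rose in 17 of 19 cases (17 adjusted over the list alone; median 1.39, adjusted p = 7.68e-15; adjusted p = 0.0533 with an estimated correlation). Among them, Msmo1 stood at 1.90 ± 0.17. FGF and ERK targets rose in 4 of 16 cases (7 with trimmed-mean factors; 4 adjusted over the list alone; adjusted p = 0.00162; adjusted p = 0.0737 with an estimated correlation). Among them, Ier3 stood at 3.73 ± 0.51 and the ERK phosphatase gene Dusp4 at 1.79 ± 0.12. LIF and STAT3 targets rose in 6 of 13 cases and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.021; adjusted p = 0.632 with an estimated correlation). Among them, Stat3 itself stood at 3.17 ± 0.21 and Osmr, a cytokine receptor of the LIF family, at 2.35 ± 0.16. Genes of the Lin28 and let-7 axis rose in 6 of 14 cases and 2 fell (1 fell with quantile scaling; 6 and 2 adjusted over the list alone; adjusted p = 0.0272; adjusted p = 0.632 with an estimated correlation). Among them, Lin28a stood at 3.32 ± 0.50 and Igf2bp3 at -2.65 ± 0.43.

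Immediate-early and heat shock genes fell in 14 of 16 cases at P20 (15 adjusted over the list alone; median -2.27, adjusted p = 6.26e-06; adjusted p = 0.253 with an estimated correlation). Among them, Hspa1a stood at -3.86 ± 0.65, Fos at -3.84 ± 0.50 and Klf2 at -3.67 ± 0.32. Early nephron differentiation genes fell in 13 of 21 cases and 1 rose (median -1.14, adjusted p = 0.00162; adjusted p = 0.253 with an estimated correlation). Among them, the Notch target Heyl stood at -3.77 ± 0.22, Clec18a at -2.98 ± 0.35 and Fgf8 at -2.77 ± 0.35. Wnt4 fell by 1.68 ± 0.52 (adjusted p = 0.0234), a call that ended without the E11.5 line (-1.26, adjusted p = 0.107), the E13.5 line (-1.62, adjusted p = 0.0711) or the E16.5 line (-1.71, adjusted p = 0.0594), and with no age term (adjusted p = 0.0705) or the line as a random effect (adjusted p = 0.0651). Lef1 fell by 1.40 ± 0.16 (adjusted p = 3.01e-05). Cap mesenchyme genes moved both ways, 13 of 30 lower and 4 higher (the same counts adjusted over the list alone), and the list did not pass (adjusted p = 0.0738). Spock2 (-3.01 ± 0.21) and Bmp7 (-2.85 ± 0.26) were among those that fell. Markers of other kidney cells were lower too. Stroma genes fell in 9 of 17 cases and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.00554 by camera, adjusted p = 0.632 with an estimated correlation). Foxd1, the transcription factor of stromal progenitors, stood at -3.65 ± 0.14 and Penk at -4.08 ± 1.05. The fall of Penk rests mainly on the late ages, as its primary values averaged 76.8 ± 96.9 RPKM (SD, n = 8) and went down to 0.806. Macrophage genes fell in 7 of 14 cases (7 adjusted over the list alone, adjusted p = 0.0118 by camera, adjusted p = 0.674 with an estimated correlation). Among them, Tyrobp stood at -4.00 ± 0.87. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, fell in 9 of 12 cases (3 with quantile scaling; 10 adjusted over the list alone; adjusted p = 0.00344; adjusted p = 0.253 with an estimated correlation).

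In total 4916 of 13612 genes passed at P20, 1974 higher and 2942 lower. The split depended on the scaling of the libraries. The share of higher calls was 40.2% as deposited, 54.1% with trimmed-mean factors and 51.7% with quantile scaling, and the median change of all genes moved from -0.11 to -0.004 and -0.029. The list medians named here as risen or fallen kept their sign under both scalings. On the authors' signature list, 139 of the 312 tested symbols with a higher mean in NPCs fell and 36 rose (145 and 37 adjusted over the list alone), and of the 766 with a higher mean in Six2-negative cells 135 rose and 166 fell (138 and 172 adjusted over the list alone). That list probably rests on these primary libraries and is no independent evidence of direction.

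At P80 the comparison with the same 8 primary libraries gave 5351 called genes of 13612, 2083 higher and 3268 lower, and the share of higher calls was 38.9% as deposited, 52.5% with trimmed-mean factors and 49.7% with quantile scaling. The glucose, p53 and sterol genes were again high. Anxa1 rose by 6.29 ± 0.75 to 248.3 ± 84.6 RPKM (SD, n = 4), Slc2a3 by 5.54 ± 0.34 (adjusted p = 1.98e-07), Matn1 by 5.26 ± 0.26, the prolyl hydroxylase gene Egln3 by 5.11 ± 0.59, Nxph4 by 4.93 ± 0.45 and the protease inhibitor gene A2m by 4.68 ± 0.28. Fosb fell by 5.72 ± 0.68, Meox1 by 4.96 ± 0.27, Ppp1r1a by 4.67 ± 0.32, and Nr2f1 by 4.31 ± 0.18. Pax2, a transcription factor needed for nephron formation, fell by 4.28 ± 0.76 (adjusted p = 0.000778). It averaged 116.9 ± 27.1 RPKM (n = 8) in primary cells and 16.53 ± 28.8 RPKM (n = 4) in the lines at P80. The fall was uneven, as the E16.5 line kept a far higher level of Pax2 than the other lines. Glycolysis and hypoxia genes rose in 21 of 22 cases (22 adjusted over the list alone; adjusted p = 0.00472 with an estimated correlation), p53 targets in 18 of 20 (18 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation), cholesterol synthesis genes in 17 of 19 (17 adjusted over the list alone; adjusted p = 0.0498 with an estimated correlation) and FGF and ERK targets in 8 of 16 (9 adjusted over the list alone; adjusted p = 0.0444 with an estimated correlation). Lin28a rose by 3.17 ± 0.50 and Stat3 by 3.14 ± 0.21.

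Wnt targets fell in 11 of 15 cases at P80 and 2 rose (11 and 2 adjusted over the list alone; median -0.78, adjusted p = 0.00979; adjusted p = 0.432 with an estimated correlation). The cyclin D1 gene Ccnd1 (-3.72 ± 0.22), the Wnt antagonist gene Notum (-1.98 ± 0.31) and Lef1 (-1.83 ± 0.16) fell. Early nephron differentiation genes fell in 14 of 21 cases and 1 rose (16 and 2 adjusted over the list alone; adjusted p = 0.000282; adjusted p = 0.2 with an estimated correlation), with Wnt4 at -3.40 ± 0.52 (adjusted p = 0.000269). Immediate-early and heat shock genes fell in 13 of 16 cases (14 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), histone genes in 11 of 12 (6 with quantile scaling; 11 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), macrophage genes in 8 of 14 (8 adjusted over the list alone; adjusted p = 0.74 with an estimated correlation) and stroma genes in 9 of 17 with 1 riser (11 and 1 adjusted over the list alone; adjusted p = 0.74 with an estimated correlation). Tubule genes fell in 6 of 17 cases (6 adjusted over the list alone; adjusted p = 0.021; adjusted p = 0.74 with an estimated correlation). Among them, Krt8 stood at -2.83 ± 0.66. Of the posterior Hox genes, Hoxb9 (-2.78 ± 0.46) fell and Hoxd13 (2.28 ± 0.53) rose, and the list did not pass. Signature symbols with a higher mean in NPCs fell in 152 of 312 cases and rose in 32 (158 and 37 adjusted over the list alone), with the same limit on their independence.

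**Figure D3:**
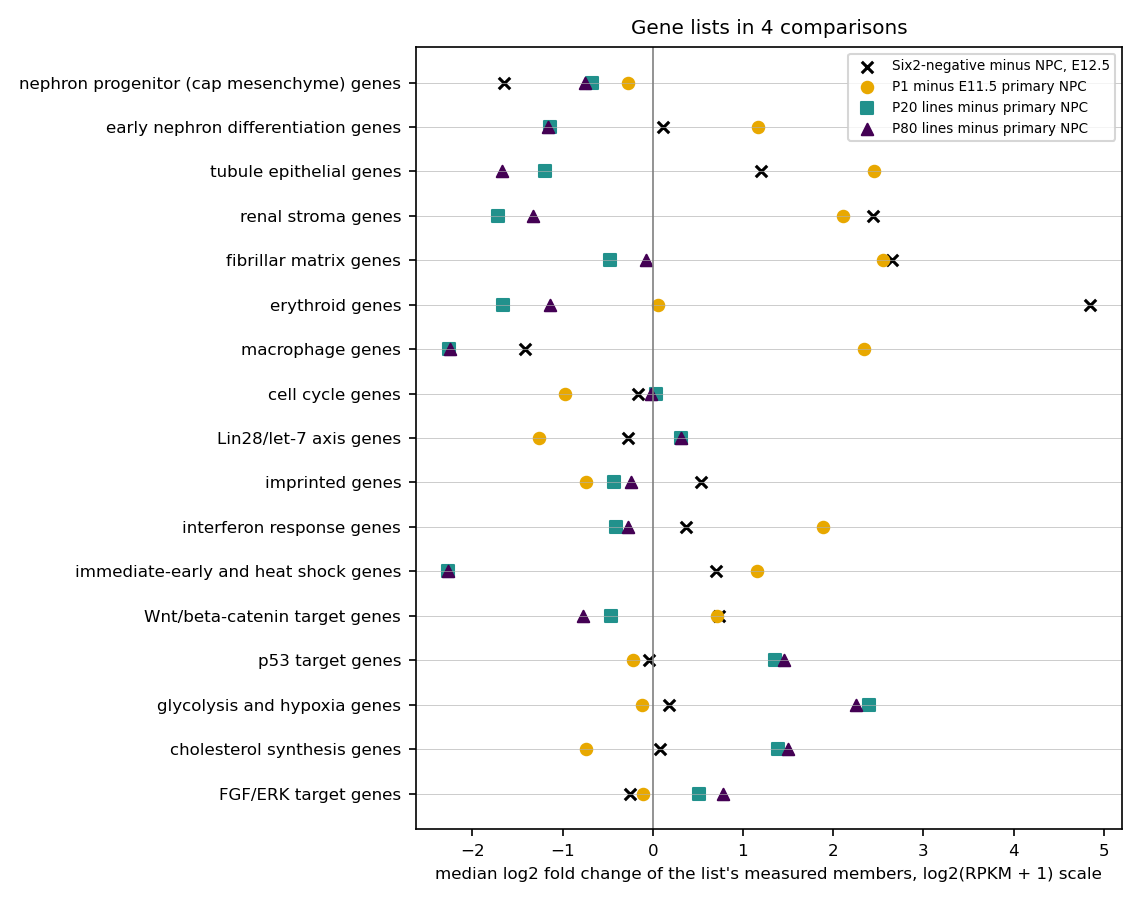
Median log2 fold change over the measured members of 17 gene lists in 4 comparisons, on the log2(RPKM + 1) scale, with 1 symbol per comparison. Glycolysis and hypoxia genes lie at 2.40 and 2.26 in the lines at P20 and P80 and near 0 in the other comparisons; other scalings turn the sign of the medians of early nephron genes in Six2-negative cells, erythroid genes at P1, cell cycle genes at P80 and fibrillar matrix genes at P80.

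The 4 lines were compared with themselves between P80 and P20 to ask whether long passaging moved them further. No gene passed in limma (smallest adjusted p = 0.8), and 819 of 13612 genes, or 6.0%, had an unadjusted p under 0.05. The term for age of origin is shared with the primary libraries, so the error also holds differences between lines. On simulated data of this design with 100 genes changed by a log2 of 2, 94% were recovered. Those were better expressed genes changed alike in all lines, so the share does not cover changes in single lines. Without the E16.5 line at P80, 6 genes passed. Six2 differed by 0.22 ± 0.22 (adjusted p = 0.861), Cited1 by 0.01 ± 0.41 and Lef1 by -0.43 ± 0.19 (adjusted p = 0.8). Pax2 (-1.99 ± 0.88, adjusted p = 0.8) and Wnt4 (-1.72 ± 0.60, adjusted p = 0.8) had lower means at P80, with single lines apart: Pax2 went from 73.3 to 3.77 RPKM in the P1 line and from 15.1 to 0.241 in the E13.5 line, and from 69.7 to 59.7 in the E16.5 line. The lists of Wnt targets, BMP and SMAD targets and respiratory chain genes passed as lower, and fibrillar matrix genes as higher, with no member called. Their adjusted p was 0.00522, 0.0105, 0.00522 and 0.0326, and with an estimated correlation the adjusted p = 0.894, 0.894, 0.966 and 0.966. Among the lines, P20 and P80 libraries also fell into different sets by how the last lines of the table were filled. With a term for the set, which the primary libraries allow to be estimated, 0 genes passed as well.

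The age of origin was then followed into culture by comparing late (E16.5 and P1) with early (E11.5 and E13.5) cells, in primary libraries and in lines. P20 and P80 of each line were averaged, which leaves 2 lines in each age class. In primary cells 3367 genes passed, 2071 higher and 1296 lower at the late ages, and in lines 6 passed, with 1158 genes, or 8.5%, at an unadjusted p under 0.05. These counts cannot be set against each other as amounts of change. Primary cells entered as 8 libraries, with the 2 of each age counted as separate values, and lines as only 4 averages. The called genes in lines were Cdkn2a, Saa3 and Slco3a1 and the microRNA gene Mir7087, higher in late lines, and Mir7030 and Mir18b, lower; the microRNA genes were named after their values were seen, and so was Slc34a1 below. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, was at 0.252 RPKM or lower in all primary libraries. In lines it was at 4.54 and 4.55 RPKM for E11.5 origin (P20 and P80), 7.98 and 10.99 for E13.5, 61.4 and 46.9 for E16.5 and 60.8 and 21.95 for P1. Its late minus early difference in lines was 2.58 ± 0.28 (adjusted p = 0.00533), and without the P1 line at P20 it was 2.22 (adjusted p = 0.21). Over the 3367 genes, the late minus early differences in lines and in primary cells had a Pearson correlation of 0.112 across genes, and 58.9% shared their direction. The genes higher at late ages had a median difference of 0.96 in primary cells and 0.07 in lines, and those lower had -0.60 and -0.03. The genes were chosen and split by their call in primary cells, so a smaller difference in lines is in part built in. The line averages also include the P1 line at P80, which lay with the lines of early origin.

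The difference between these differences was tested directly, and 97 genes of 13612 passed, 18 higher and 79 lower in lines. Most of them rose with age in primary cells and were flat or opposite in lines. Penk had a late minus early difference of 5.74 ± 0.46 in primary cells and -0.005 ± 0.66 in lines (difference -5.74 ± 0.80, adjusted p = 0.0138). Slc34a1, the phosphate transporter of the proximal tubule, had a difference of -4.00 ± 0.25 (adjusted p = 2.7e-05). Fibrillar matrix genes were lower in 6 of 15 cases (3 with quantile scaling; 14 adjusted over the list alone; median -3.69; adjusted p = 0.455 with an estimated correlation), stroma genes in 6 of 17 with none higher (11 and 1 adjusted over the list alone; adjusted p = 0.455 with an estimated correlation) and tubule genes in 2 of 17 (1 with quantile scaling; 4 adjusted over the list alone; adjusted p = 0.729 with an estimated correlation). Cap mesenchyme genes had a median of 0.54 with 1 member called (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.00467; adjusted p = 0.729 with an estimated correlation). That member was Pax2, at -0.06 ± 0.35 in primary cells and 3.15 ± 0.50 in lines (3.21 ± 0.61, adjusted p = 0.0457). It was not called with quantile scaling. The Pax2 call ended without E11.5 library 1 (3.26, adjusted p = 0.108) or 2 (3.25, adjusted p = 0.108), E13.5 library 1 (3.14, adjusted p = 0.0723) or 2 (3.20, adjusted p = 0.112), E16.5 library 1 (3.19, adjusted p = 0.0691) or P1 library 2 (3.39, adjusted p = 0.0553). It also ended without the E13.5 line at P80 (2.29, adjusted p = 0.263), the E16.5 line at P80 (3.27, adjusted p = 0.0518) or the P1 line at P20 (2.22, adjusted p = 0.444). Six2 (0.57 ± 0.37), Cited1 (-1.17 ± 0.57), Wnt4 (1.39 ± 0.57) and Lef1 (-0.32 ± 0.38) did not pass, though Wnt4 did without the P1 line at P80 (2.39, adjusted p = 0.0378).

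These counts rested on single libraries. With the P20 libraries of the lines only, 353 genes in place of 6 passed, sharing 3 of the 6, and 371 in place of 97; with the P80 libraries only, 25 in place of 97 passed. Without the P1 line at P80, 541 genes in place of 6 passed between late and early lines, and 712 in place of 97 passed for the difference between lines and primary cells. The count of 6 became 32 without the E13.5 line at P20 and 3 without the P1 line at P20. The count of 97 became 201 without the E13.5 line at P20, 51 without the E13.5 line at P80, 25 without the P1 line at P20, 29 and 27 without E11.5 libraries 1 and 2, 24 without E13.5 library 2, 64 and 871 without E16.5 libraries 1 and 2, and 303 and 58 without P1 libraries 1 and 2. The count of 3367 became 1188 and 1276 without E11.5 libraries 1 and 2, 1805 and 1280 without E13.5 libraries 1 and 2, 5561 without E16.5 library 2 and 1932 without P1 library 2. Quantile scaling changed the share of higher calls from 18.6% of 97 to 38.6% of 57, moving the median of all genes from -0.01 to 0.12, and from 61.5% of 3367 to 38.5% of 3275; trimmed-mean factors gave 50.3% of 3790 for the latter.

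Finally, single components were left out of the medium of cultures labelled E13.5 to see which of them hold the progenitor state. Each condition had 1 library, so the values below have no replicate error and no test, and each is a log2 difference from the median of the other withdrawal libraries of that day. Genes were counted if at least 1 log2 unit apart the same way on both days, with a mean RPKM of at least 5 on either side. These were 359 higher and 268 lower without BMP7, 138 and 49 without CHIR, 85 and 98 without Y27632 and 58 and 91 without heparin. On day 8 alone they were 378 and 305 without LIF. Without BMP7, Cited1 stood at 6.36 RPKM on day 4 and 2.76 on day 8, against 45.3 to 199.6 in the other withdrawal libraries (differences -3.77 and -4.26). Sall1, a zinc finger factor of progenitors, was at 2.24 and 1.64 RPKM there, against 6.05 to 28.4 in the others. The position genes Hoxc10 (-3.60 and -4.76) and Hoxd12 (-3.89 and -3.58) were low with them, and the 14 posterior Hox genes had a median of -1.68 on day 4 and -1.66 on day 8, below all 10000 random lists of matched size and level. BMP and SMAD targets had medians of -0.50 and -0.38 without BMP7, at percentiles 0.45 and 0.31 of such lists. The macrophage and stroma marker lists were high in the same 2 libraries. Macrophage genes stood at 2.19 and 1.38 (5 measured, percentiles 99.96 and 99.76). Stroma genes stood at 0.61 and 0.81 (percentiles 99.98 and 100), or 1.58 and 1.87 against the E13.5 lines. The acute phase gene Saa3 reached 1642 and 1172 RPKM without BMP7, against 1.13 to 237.9 elsewhere, and Hp (6.01 and 6.44) and the collagen gene Col3a1 (5.28 and 5.20) were also higher. Glycolysis and hypoxia genes had medians of -2.27 and -0.64 without BMP7 and -1.35 on day 8 without CHIR.

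Without CHIR, an activator of Wnt signalling through GSK3, Six2 was at 166 RPKM on day 4 and 74.2 on day 8, against 168.5 to 172.9 on day 8 without heparin or Y27632. Pltp (-2.07 and -2.15) and Sema3c (-1.84 and -1.85) were lower and Gdpd2 (3.06 and 2.96), Cbln4 (3.04 and 2.81) and the adhesion molecule gene Vcam1 (3.16 and 2.35) higher, although another withdrawal library exceeded both values of each of these 3 genes (27.8, 19.6 and 50.5 RPKM). The 14 Wnt targets measured had medians of -0.01 and 0.23 without CHIR, at percentiles 42.0 and 88.9, and fibrillar matrix genes had 1.06 on both days. Meox1 stood at 52.5 and 36.9 RPKM without BMP7, at 50.7 and 10.6 without CHIR and at 11.7 without LIF, against 1.75 to 2.25 without heparin or Y27632. Without LIF, the targets of LIF and STAT3 had a median of -1.34 on day 8, below all 10000 random lists. The same list stood at 1.02 without BMP7 and 1.20 without CHIR on that day, which are part of the reference. Against the E13.5 lines it stood at -0.75 without LIF, 0.38 without BMP7 and 0.57 without CHIR. Stat3 was at 22.1 RPKM without LIF against 54.8 to 97.8 in the other withdrawal libraries. Lin28a was at 0.357 RPKM without LIF against 8.01 to 43.3 (-4.60), Wt1, a regulator of kidney progenitors and podocytes, at 10.1 against 43.7 to 97.4, and Six2 at 79.6. Mmp13 (-5.02, but -2.08 against the E13.5 lines) and A2m (-4.22) were lower without LIF, and the Wnt antagonist gene Dkk1 was higher, at 106.7 RPKM against 0.0264 to 6.99 (6.56). Pax2 was at 1.97 RPKM or lower in all 9 withdrawal libraries, and Lef1 reached 5.06 RPKM on day 8 without BMP7. Wnt4 was at 3.86 RPKM or lower in all of them.

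Libraries without heparin or Y27632 stayed closest to the E13.5 lines, with Spearman correlations of 0.939 to 0.952, against 0.863 to 0.879 without BMP7, 0.909 and 0.918 on day 4 and 0.851 and 0.865 on day 8 without CHIR, and 0.884 and 0.887 without LIF. The withdrawal libraries are labelled total RNA and the lines poly(A) RNA, so every comparison with the lines also spans a difference in RNA type. Against the lines, further list medians moved by more than 1.5 times: Wnt targets to -0.06 on day 4 without CHIR, glycolysis and hypoxia genes to -1.55 on day 8 without BMP7 and -2.55 on day 8 without CHIR, BMP and SMAD targets to -0.65 on day 8 without BMP7, and fibrillar matrix genes to 1.90 and 2.29 without CHIR. The named differences of the heparin and Y27632 libraries hold against the other withdrawal libraries only. Without heparin, Bcam (2.16 and 3.01; up to 26.0 RPKM in another withdrawal library, against 18.1 and 25.8) was higher and Vcam1 (-3.90 and -4.53) and Hopx (-4.46 and -2.96) lower, and without Y27632 the small proline-rich protein gene Sprr1a (3.50 and 4.90) was higher and Vcam1 (-3.16 and -4.04) lower. Set against the E13.5 lines at P20 and P80 instead, all of these changed sign, for example Sprr1a at 223.9 and 69.2 RPKM without Y27632 against 437.3 and 379.9 in the lines.

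**Figure D4:**
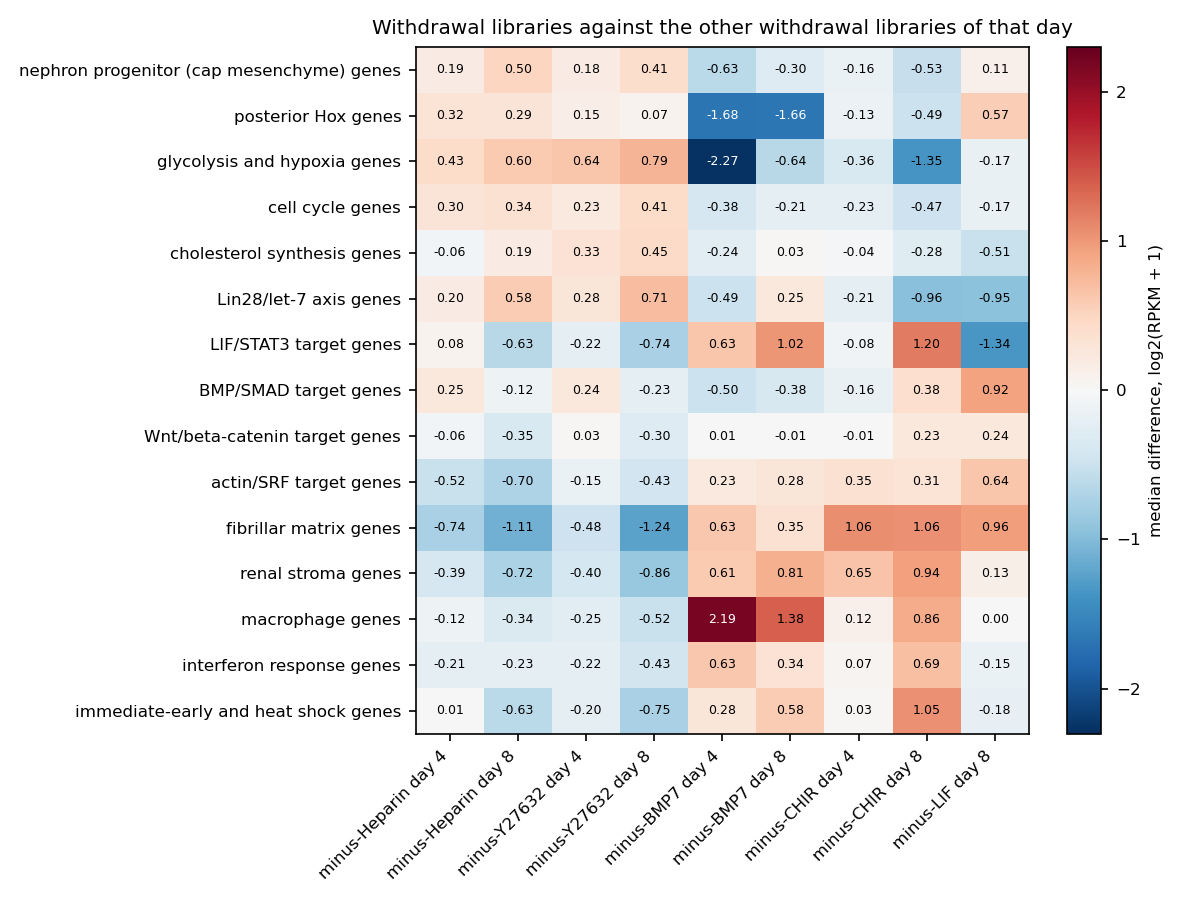
Median log2 difference of 15 gene lists in each of the 9 withdrawal libraries from the median of the other withdrawal libraries of the same day; red is higher and blue lower, and each cell gives its value. Posterior Hox genes lie at -1.68 and -1.66 without BMP7, and LIF and STAT3 targets at -1.34 without LIF.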

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

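The tests of explanations weighed here, and the contrast of late against early primary cells, were chosen after the results were seen, and the other splits of the line comparisons were planned before. The 97 genes whose late minus early difference differed between lines and primary cells were marked because the groups moved apart there. A candidate explanation for the 79 lower ones is RNA from other kidney cells in the late primary libraries. At E12.5 these genes had a median log2 difference of 0.96 between Six2-negative cells and NPCs, against -0.054 to 0.205 for matched genes, with 34 of 76 tested genes higher and none lower, which goes with that explanation. Lists of other cell types did not all move alike in late against early primary cells. Medians were 2.07 for stroma, 2.19 for tubule, 1.71 for endothelial, 2.15 for macrophage and 1.92 for ureteric bud genes. They were 0.25 for podocyte, -0.68 for skeletal muscle and -0.812 for neural and neural crest genes. A loss of progenitor share that raised every list alike is argued against by the lists that fell. A loss that raised only the lists that rose stays open. The deposited scaling is argued against as the whole cause by the size of the differences. Their median went from -2.20 (median SE 0.37) to -1.98 (0.37) under quantile scaling. Their calls depended on it more, with only 34 still called there and 73 with trimmed-mean factors. All 79 stayed below -0.5, but this decides little, since none was above -1.07 as deposited. Real change with age in the progenitors stays open and was not tested.

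The genes lower in lines at P20 might likewise reflect Six2-negative RNA in the primary libraries. This cannot be told apart: over the 2942 genes the median difference between Six2-negative cells and NPCs was -0.026, with 280 called higher and 263 lower, and a median over genes that go both ways decides nothing. The deposited scaling could account for part of the 2942, of which 1982 were still called lower under quantile scaling, so it is argued against as the whole cause.

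The P1 line at P80 lay with the lines of early origin, with a mean Pearson correlation of 0.961 with them and 0.92 with the other late lines. Its closest line library was the E11.5 line at P80 (0.969). That library was closer to the P1 line at P80 than to the E11.5 line at P20 (0.96). A swap with another line library is argued against, as 0 libraries labelled early correlated better with late lines. A shift shared by its set of libraries is argued against by the correlation of 0.951 of the E16.5 line at P80 with late lines, against 0.926 with early ones. A wrong label on a P80 culture of another line cannot be told apart: Eif2s3y, a Y chromosome gene, was at 0.038 RPKM but moved from 13.9 to 0.029 between passages of the E13.5 line, so it does not decide for the E11.5 or E16.5 line, and for the E13.5 line the 2 deviations from the mean of the lines correlated at 0.29, with 0.297 as the highest of the others. Drift during passage may also be at work and was not tested.

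In other splits of the same libraries, as many calls as in the real one came up in 1 of 100 splits for P20 lines against primary cells. That was the real split itself (4916 genes, highest other 2809). For P80 lines it was also 1 of 100 (5351 genes, highest other 2986). These splits were drawn without regard to age or to the 2 libraries per age, and every other split mixed lines with primary cells. The count therefore cannot exclude chance. For late against early primary cells it was 1 of 35 (3367 genes; highest other 2), but only 3 of those splits keep the 2 libraries of each age together, which are too few for a share under 0.05. For P80 against P20 lines this count decides nothing, since the real split has 0 genes and all 35 splits have at least as many. The highest other has 917 genes and sets early against late lines, a structure of the samples. With age of origin in that fit, its contrast is the early against late difference in lines relative to primary cells. P20 and P80 of a line count there as separate libraries.

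Single lines stood apart from the other 3 in 10 of the 60 groups of 4 looked at. A gap this wide comes up by chance in about 1 of 20 groups of independent, normal values. The groups here are the same genes at both passages, and most of those flagged come from the E16.5 line at P80. An excess over chance is therefore not shown. Several values lie near the floor, such as Nr2f1, at most 0.04 RPKM in the other lines at P20 and 0.05 at P80. In the E16.5 line at P20, Nr2f1 was at 0.862 RPKM, and in the P1 line at P20, Hsd11b2 was at 4.72. In the E16.5 line at P80, Aldoc was at 142.7, Fosb at 26.97, Dhrs3 at 0.1645, Nr2f1 at 0.9311, Ppp1r1a at 2.288, Pnmt at 1.583 and Ackr3 at 2.545 RPKM. In the E13.5 line at P80, Penk was at 0.07496 and at 0 in the others. Each gene stayed called without that line.

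Of the genes whose late minus early difference was larger in lines, the marked ones were Arg1 (4.14), Pax2 (3.21), Dusp5 (2.76), Slco3a1 (2.71), Saa3 (2.63), Irx4 (2.54), Cdkn2a (2.47), Sst (2.34), Kcne1l (2.22) and Slc16a6 (2.18). Those with a smaller difference in lines were Penk (-5.74), Ly6a (-5.35), Igfbp7 (-5.34), Postn (-5.06), Col3a1 (-4.97), Hbb-bt (-4.88), Emp1 (-4.78), Dcn (-4.73) and Col1a2 (-4.72). They were marked because lines and primary cells differed in them.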

How the results depend on the processing

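The alternatives for the set of the shifted lines, E16.5 in place of P1, early ages only and the separate late against early contrasts were chosen after the results were seen, and the others before. Of 565 called gene values, 326 kept their call under every alternative, 239 lost it under at least 1 and 0 turned direction. The cause was not tested for any of the changed results here.

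The 97 genes with a different late minus early difference in lines became 225 with a pseudocount of 0.1, 47 with a pseudocount of 5, 56 with a filter at an RPKM of 5, 57 with quantile normalization, 371 with P20 libraries only and 25 with P80 libraries only. The 6 genes between late and early lines became 17 with either pseudocount, 23 with no filter, 14 with the stricter filter, 22 with no variance trend and 353 with P20 libraries only. A minimum fold of 2 left 1180 genes for Six2-negative cells, 2017 for P1 against E11.5, 2052 for the 5 ages, 1622 for P20, 1757 for P80 and 1122 for late against early primary cells. E16.5 in place of P1 gave 234 genes against E11.5.

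With an estimated correlation the lists called went from 14 to 0 for Six2-negative cells, 15 to 0 for P1 against E11.5, 12 to 2 for P20, 13 to 4 for P80, 4 to 0 for P80 against P20 and 12 to 0 for the late minus early difference. With no filter the correlation of lines with primary libraries was 0.919 in place of 0.881 and that of primary with Six2-negative libraries 0.932 in place of 0.9.

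With single libraries left out, counts ran from 400 to 2397 for Six2-negative cells, 1427 to 6376 for P1 against E11.5, 1231 to 5632 for the 5 ages, 0 to 6 for P80 against P20, 24 to 871 for the late minus early difference, 1188 to 5561 for late against early primary cells and 3 to 541 for late against early lines. A replicate block gave 1874 genes for Six2-negative cells, 4842 for P1 against E11.5 and 3094 for the 5 ages. Between lines and primary cells no paired analysis was possible because the labels of the lines carry no replicate numbers. The P80 against P20 estimate sets each line against itself, but its error does not rest on the lines alone. The term for age of origin is shared with the primary libraries. Differences between lines that primary cells of those ages lack therefore stay in the error. With the line as a random effect, in a fit that also holds the primary libraries, 0 genes passed as well. The deviations of libraries with the same number correlated at -0.109 to 0.374 over 15 pairs of groups, 7 of them over 0.1, and in all 6 groups the best match had the same number, a weak hint from the data, since the 2 libraries of a group mirror each other by construction. A term for the set of the shifted lines gave 1854, 4871 and 3093 genes for the same comparisons and 4013 for P20 and 4212 for P80, and early ages only gave 6454 and 6755 for these.

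With the E13.5 lines as reference, 149 genes were higher without heparin in place of 58. Without BMP7 686 were higher and 467 lower, without CHIR 524 and 215, and without LIF 798 and 557. Against those lines the smaller differences turned direction without heparin for Smim22 (-0.696), Gpx6 (-2.694), Bcam (-0.622), Vcam1 (0.317), Hopx (0.214) and Gdpd2 (0.135), and without Y27632 for Sprr1a (-2.541), Stmn2 (-0.336), Vcam1 (1.054), Gdpd2 (0.147) and Hopx (1.375).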

Other observations

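The observation here was made after the results were seen, and no test was planned for it. The Y chromosome gene Eif2s3y differed within lines, from 13.9 RPKM at P20 to 0.029 at P80 in the E13.5 line, and from 36.1 to 13.2 in the E11.5 line. In the P1 line it was at 0.523 and 0.038, and Xist was present in all 8 line libraries at 17.2 to 63.6 RPKM. No test was run on these genes in single lines, and genotyping single cells of each line for sex at both passages would show whether the cultures are mixed.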
